A study of Mus musculus with 2 samples.

How the data were processed

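Hippocampus RNA of 6-month-old mice was profiled by long-read RNA sequencing in 2 libraries of 1 group. The group and the replicate numbers were taken from the labels, which number the libraries as biological replicates 1 and 2, give them separate biosamples and 1 shared donor identifier, describe the mice as male and leave the field for sex without a value. No second condition is labelled, so every comparison is between the 2 libraries, and its test compares the libraries, not conditions.

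The deposited tables hold raw counts of long reads per transcript model, 1 table per library, with no normalization by the authors. Whole numbers of 1 or more fill the count column, so models without reads are not listed. Models were made with TALON, a program that places each long read on an annotated or a new transcript model, per the file headers of the deposited annotations. Per the description files deposited with the data, the build was mm10 and the annotation GENCODE M21. The aligner, the version of TALON, the sequencing platform, the filters and the strand setting of the library preparation are not given in the sources used here. The deposited tables also give each model's class, number of exons and length in bases, and the deposited annotations give the 1-based coordinates of exons. Checksums in the description files matched for 4 of 4 files. TALON's classes are annotated transcripts, incomplete matches to an annotated transcript, unannotated combinations of annotated splice sites, models with an unannotated splice site, genomic reads, antisense loci and intergenic loci. Unspliced reads can be placed in several of these classes.

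Replicate 1 had 1330153 reads and replicate 2 had 1366252. A single read supported 58.6% and 58.2% of the models. The floor of 3 reads for a count of 0 corresponded to 2.26 CPM in replicate 1 and 2.20 CPM in replicate 2. Annotated genes held 94.2% and 96.6% of reads, with a median of 15.0 and 16.0 reads per detected gene. At least 10 reads fell on 9929 and 9935 genes, so levels of the remaining genes rest on few reads. Molecular identifiers are not described, and intervals and floors cover counting error only.

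Gene counts were the sums of a gene's models of every class. CPM used all reads of the library as the total. Gene positions were taken from GENCODE M21, which holds 18584 of the 18595 detected genes, because the span of the deposited gene line differed from it for 11748 genes. This choice was made after the files had been read. Shares of reads were given with exact Clopper-Pearson 95% intervals. Each gene with at least 10 reads over both libraries was tested with a two-sided Fisher's exact test of its reads against the rest of each library, with Benjamini-Hochberg adjustment at 0.05. A ratio against a count of 0 was computed against the floor of 3 reads per library and is a lower bound. The common dispersion of the 1 group came from edgeR with an intercept alone, and edgeR's exact test with that dispersion and TMM library sizes was added after the data had been seen. The dispersion was estimated from the same 2 libraries, so real differences between them raise it.

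The gene lists, the Fisher's exact tests, the list percentile and most of the other settings tried were fixed before the data were examined, and later choices are named as such. There were 32 lists: 20 of cell types and regions (pan-neuronal, glutamatergic, GABAergic, dentate gyrus granule cell, CA1, CA2, CA3, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural, choroid plexus, ependymal, meninges fibroblast, thalamus, isocortex, striatum and blood) and 12 of other groups (female X-inactivation, Y-linked, immediate early, heat shock and hypoxia, mitochondrially encoded, respiratory chain, glycolysis, presynaptic vesicle, postsynaptic density, channels, Alzheimer's disease and long noncoding RNA). A list with at least 3 testable members was described by its median log2 ratio of CPM + 1. This was ranked among 10000 random lists of the same size, drawn for each member from the 100 genes on either side in mean CPM.

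Models were matched between libraries by strand, chromosome and chain of introns, since identifiers of unannotated models are specific to a library. Matching ignored the class, and unspliced incomplete reads were pooled as 1 model per gene. Both rules were set after the data had been seen, because keys kept apart per library gave shares of 100% against 0%. The leading model of a gene was the one with most reads over both libraries, genomic reads left out, among genes with at least 20 reads in each library, and its share was compared by Fisher's exact test. Unannotated spliced models and loci needed 2 reads in each library. Shared sequence between genes was measured as the percentage of 25-base words of the annotated transcripts of one gene that occur in those of the other.

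Named genes followed a fixed rule. It took the 20 nuclear genes of highest mean CPM, the 3 highest members of each list, and all members of lists of 4 or fewer. Between libraries it took the 10 genes with the largest ratio each way among those past the test with at least 100 reads over both. It also took the 15 isoform genes with most reads in full, the 10 largest differences in leading share, the 10 unannotated spliced models and the 10 genes led by one with most reads, and 5 loci of each kind. Exceptions, chosen after their values were seen, were Ddn, Kcne2, Pde2a, Gapdh, Nme7, mt-Atp6 beside Gm10925, the X-linked homologs, genes named for a change of direction or as the only call of a list, isoform genes outside the 15, and genes with several annotated transcripts. Families and single genes in the last part of the closing section were chosen in the same way.

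Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. The steps were tested on simulated data for the gene comparison, with 200 genes changed by known folds. With counting error alone, Fisher's exact test called 4 unchanged genes of 11864 tested, and recovered 14.9%, 41.8% and 93.9% of genes changed 1.5-, 2- and 4-fold. With the estimated dispersion added it called 1045 unchanged genes of 11823, while edgeR's exact test called 1 and recovered 0%, 5.97% and 63.6%. A dispersion corresponding to a coefficient of variation of 16.1% was estimated as 18.5%. For the leading share, 49.0% of genes changed by 30 percentage points were recovered, 97.4% of those with at least 100 reads in each library, and 3 unchanged genes of 6262 were called. Of 200 random lists, 5% lay outside the central range.

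Alternatives covered the scaling (edgeR's TMM, DESeq2's size factors and reads on annotated genes), minimum reads, the pseudocount, leaving out genomic, incomplete or mitochondrial reads, the choroid plexus list left out of the totals, annotated transcripts alone, matching by identifier, overlap rules for loci, counting each model once, and each library alone. Values of some genes that the rule takes are not reported here, and these genes are left out of the counts of alternatives for single genes. Alignments were not used here, and no genome sequence was used.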

Results

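Long-read RNA sequencing was carried out on hippocampus of the mouse, the brain region of the dentate gyrus and the CA fields. Long-read sequencing reads a transcript from end to end, so that each read is placed on 1 transcript model with its own chain of introns. The tissue came from adult mice of the C57BL/6 background (strain B6NCrl), 6 months of age and labelled male. The labels give 1 group of 2 libraries, called replicate 1 and replicate 2, and there is no second condition. The account below therefore describes the transcripts of this tissue and how far the 2 libraries differed. The labels give each library its own biosample but the same donor identifier, and do not say whether 2 animals were sampled, so a difference between them may be technical. Fisher's exact test sets such a difference against counting error alone. Replicate 1 held 1330153 reads and replicate 2 held 1366252, on 133886 and 133393 transcript models. Levels are in CPM, counts scaled to a library of 1000000 reads. In replicate 1 a single read was worth 0.752 CPM, and in replicate 2 it was worth 0.732 CPM. Values are given as mean ± SD (n = 2) unless stated otherwise, intervals are exact Clopper-Pearson 95% intervals or follow from them, and intervals and floors cover counting error only. All coordinates are of the mouse build mm10 (GRCm38), and gene positions are those of the GENCODE M21 annotation.

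Most reads came from annotated transcripts of annotated genes. Transcripts already in the annotation held 68.2% ± 2.72 of the reads, and models that matched an annotated transcript incompletely held 13.7% ± 0.178. Spliced models absent from the annotation were a small part: 3.33% ± 0.323 of reads joined annotated splice sites in an unannotated combination, and 2.77% ± 0.0791 used at least 1 unannotated splice site. The genomic class, nearly all of it unspliced reads within genes, held 7.44% ± 1.28. Reads on antisense loci held 4.11% ± 1.59, and reads on intergenic loci 0.412% ± 0.0684.

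Between the 2 libraries these shares differed by more than counting error, which is small at this depth. Annotated transcripts took 66.3% (66.2 to 66.4) of replicate 1 and 70.1% (70.1 to 70.2) of replicate 2. Antisense loci took 5.23% (5.19 to 5.27) against 2.98% (2.95 to 3.01), a ratio of 1.75, and the genomic class 8.34% against 6.53%, a ratio of 1.28. The largest p-value among the classes was that of unannotated splice sites, at 2.71% against 2.82% (two-sided Fisher's exact test, p = 2.18e-08). This test compares the libraries, not conditions. Single-exon models of any class held 24.5% of the reads of replicate 1 and 19.4% of those of replicate 2. Within the antisense class, single-exon models held 98.7% and 98.3% of the reads.

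**Figure D1:**
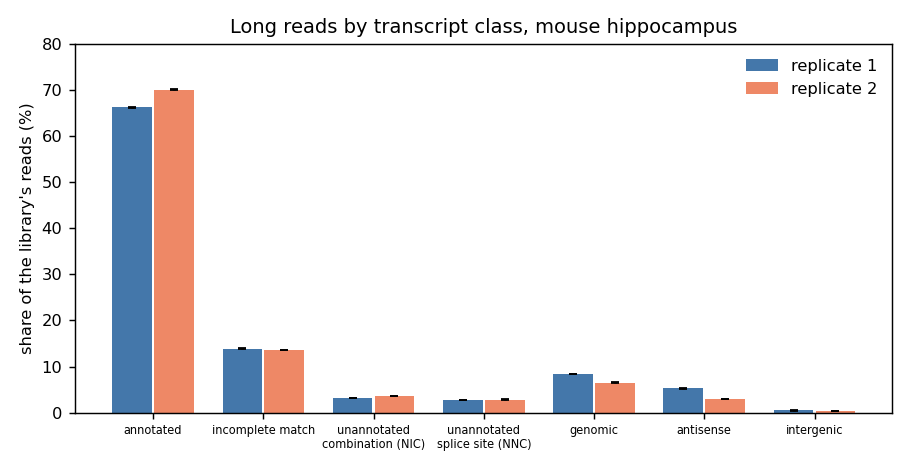
Share of each library's reads (%) in each of the 7 transcript classes, with 1 bar per hippocampus library and 95% Clopper-Pearson intervals. Annotated transcripts took 66.3% and 70.1%, and antisense loci 5.23% and 2.98%, in replicate 1 and replicate 2.

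By median length, annotated transcripts were longer than incomplete matches, genomic and antisense models, but shorter than unannotated spliced models. Weighted by reads, the median model length was 1698 ± 122 bases for annotated transcripts and 1454 ± 47.4 bases for incomplete matches. Unannotated combinations of annotated splice sites had a median of 1985 ± 75.0 bases, and models with an unannotated splice site 1794.5 ± 55.9 bases. The genomic class had a median of 1403 ± 7.07 bases and the antisense class 1348.5 ± 44.6 bases. Annotated transcripts had a median of 1612 bases in replicate 1 and 1784 bases in replicate 2.

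Both libraries detected nearly the same number of genes. At least 1 read fell on 16939 annotated genes in replicate 1 and on 16649 in replicate 2. Of the 18595 genes seen in either library, 14993 were seen in both. Genes seen in a single library had a median of 1 read, and none had more than 146. Protein-coding genes took 88.5% and 91.1% of all reads, and ribosomal RNA genes of the mitochondrion 2.32% and 2.31%. Across the 18595 genes, log2(CPM + 1) of the 2 libraries had a Pearson r of 0.954 and a Spearman rho of 0.939. These are correlations across genes, which are not independent replicates. The biological coefficient of variation between the libraries, from edgeR's common dispersion, was 16.1%. Gene counts differed by 4.71 times the chi-square expected from sampling alone, so the 2 files were not copies of 1 library and were kept as 2 samples.

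The most abundant nuclear transcripts encoded iron storage, lipid transport, chaperone, cytoskeletal and energy metabolism proteins. Fth1, the ferritin heavy chain (gene ENSMUSG00000024661.7, chromosome 19, 9980598 to 9985098), led with 8215 ± 72.7 CPM. Apoe, the main lipid carrier of the brain (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188), followed with 7661 ± 220.0 CPM. Neither differed between the libraries by Fisher's exact test adjusted over all genes, although Apoe did adjusted over its list alone. The constitutive chaperone Hspa8 had 7149 ± 1094 CPM and the protease inhibitor Cst3 had 7020.3 ± 921 CPM. Brain creatine kinase Ckb had 6249 ± 976 CPM, and the calmodulin gene Calm2 had 3647 ± 309 CPM. Among cytoskeletal genes, Tuba1a reached 4327 ± 743 CPM, Actg1 reached 3723 ± 978.5 CPM and Tubb2a reached 2974 ± 250.0 CPM. Cpe, which trims neuropeptide precursors, had 4515 ± 532 CPM, Ubb had 4066 ± 372 CPM, Aldoa had 3945 ± 302 CPM and Mbp had 3376 ± 497 CPM. Itm2b, Atp1b1 and Hsp90ab1 lay between 2927 and 3241 CPM. The level of Atp1b1 is uncertain because the gene overlaps Nme7, and levels of tubulin, actin, calmodulin and hemoglobin genes are uncertain where a read could be placed on a near-identical copy.

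Ttr, the thyroxine carrier made by the choroid plexus (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), averaged 6021 ± 8404.5 CPM, from 11964 CPM in replicate 1 and 78.3 CPM in replicate 2. Actb had 5099 CPM in replicate 1 and 2596 CPM in replicate 2, and its log2 ratio of 0.97 became -0.10 without genomic and incomplete reads, which did not pass the test. Gm10925, a pseudogene on chromosome 1 (24613974 to 24614651), had 3691 ± 408 CPM. All of its 25-base words also occur in mt-Atp6 of the mitochondrial genome, which had 3525 ± 439 CPM, so both levels are uncertain. Gapdh, often used as a reference gene, held 14 and 29 reads in the deposited counts, while 833 pseudogenes together held 2.10% and 2.08% of all reads.

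Neuronal, astrocytic and oligodendrocytic transcripts were all abundant in the tissue. Summed over the fixed marker lists, the astrocyte list reached 11257 ± 749 CPM, most of it from Cst3 (7020.3 ± 921 CPM). The glycolytic enzyme Aldoc (2008 ± 232 CPM) and the glutamate transporter Slc1a2 (563 ± 67.8 CPM) followed. Sums that rest mostly on a single gene do not rank the cell types. The pan-neuronal list reached 7861 ± 874 CPM, led by the synaptic fusion protein Snap25 (2493 ± 447 CPM), the neurofilament Nefl (1403 ± 229 CPM) and Stmn3 (979 ± 85.3 CPM). The oligodendrocyte list reached 6753 ± 1215 CPM, with the myelin genes Mbp and Cnp (956 ± 281 CPM). Glutamatergic markers summed to 1819 ± 90.9 CPM and were led by Camkv (637 ± 118 CPM), Camk2a (509 ± 30.1 CPM) and Neurod6 (184 ± 0.182 CPM). GABAergic interneuron markers summed to 1155 ± 58.4 CPM, most of it from the peptide precursor Cck (600.5 ± 34.8 CPM). The GABA-synthesizing enzymes Gad1 (226 ± 18.3 CPM) and Gad2 (105 ± 2.73 CPM) followed. Microglial markers summed to 1516 ± 164 CPM, with C1qa at 193 ± 34.6 CPM and C1qb at 149 ± 15.5 CPM.

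Markers of each hippocampal field were present at lower levels. The dentate gyrus granule cell list summed to 807.5 ± 103 CPM, with Calb1 at 363 ± 65.5, C1ql2 at 249 ± 32.0 and Stxbp6 at 63.4 ± 0.373 CPM. CA1 markers summed to 396 ± 41.8 CPM (Mpped1 111 ± 16.8, Wfs1 91.4 ± 19.8 and Fibcd1 72.6 ± 7.02 CPM). CA3 markers summed to 405 ± 11.7 CPM (Bok 210.2 ± 3.89, Cpne4 55.3 ± 1.57 and Socs2 40.8 ± 3.42 CPM). CA2 markers summed to 240.5 ± 17.1 CPM (Pcp4 175 ± 22.7, Rgs14 31.1 ± 1.51 and Amigo2 30.7 ± 5.19 CPM). Markers chosen for neighbouring regions, in lists of other sizes, summed to 313 ± 19.0 CPM for isocortex (Cdh13 79.3 ± 10.04, Etv1 58.2 ± 6.77 and Rorb 57.4 ± 34.6 CPM), 212 ± 11.2 CPM for striatum (Penk 71.8 ± 13.3, Ppp1r1b 71.2 ± 2.40 and Rasd2 18.9 ± 1.22 CPM) and 98.1 ± 16.5 CPM for thalamus (Rora 53.3 ± 14.7, Calb2 26.3 ± 1.08 and Tcf7l2 5.23 ± 4.29 CPM).

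Vascular and rare cell types gave small sums. Endothelial markers summed to 569 ± 46.9 CPM, led by the tight junction gene Cldn5 (197 ± 47.1 CPM), Pltp (141 ± 5.30 CPM) and Itm2a (98.2 ± 13.4 CPM), and mural cell markers to 124 ± 24.9 CPM, led by Vtn (63.3 ± 11.9 CPM), Rgs5 (31.1 ± 4.66 CPM) and Acta2 (7.72 ± 6.67 CPM). Oligodendrocyte precursor markers summed to 85.8 ± 27.8 CPM (Olig2 32.5 ± 17.2, Pdgfra 17.1 ± 1.37 and Neu4 9.96 ± 5.58 CPM), and ependymal markers to 57.2 ± 11.6 CPM (Rarres2 24.9 ± 9.39, Tmem212 17.4 ± 2.29 and Ccdc153 7.79 ± 0.672 CPM). Hemoglobin and other blood genes summed to 10.04 ± 2.81 CPM, with Hba-a1 at 2.99 ± 2.15, Hbb-bs at 2.97 ± 0.0562 and Hba-a2 at 2.24 ± 1.09 CPM.

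Energy metabolism genes had higher sums than synaptic genes. The glycolysis list summed to 17433 ± 1359 CPM, led by Aldoa, Aldoc and Pkm (1963 ± 205 CPM), and mitochondrially encoded protein genes to 17057 ± 3441.5 CPM, led by mt-Nd1 (4476 ± 1238 CPM), mt-Co1 (3715 ± 940.5 CPM) and mt-Atp6. Nuclear-encoded respiratory chain genes summed to 12824 ± 467 CPM, led by Cox4i1 (1925.5 ± 37.5 CPM), Atp5a1 (1794 ± 209 CPM) and Atp5b (1615 ± 124 CPM). Genes of Alzheimer's disease risk and amyloid summed to 14031 ± 456 CPM, most of it from Apoe and Itm2b, with App at 909 ± 102 CPM. Presynaptic vesicle genes summed to 6560.5 ± 671 CPM (Snap25, Rab3a 687 ± 91.9 and Cplx2 630.1 ± 115 CPM), and postsynaptic density genes to 2883 ± 68.1 CPM (Gria2 552 ± 4.24, Camk2a, and Camk2b 439 ± 28.9 CPM). Potassium and sodium channel genes summed to 1181 ± 240.5 CPM (Scn2b 594.5 ± 231 and Scn2a 115 ± 8.47 CPM). Heat shock and hypoxia genes summed to 8085 ± 1141 CPM, most of it from Hspa8, with Hsp90aa1 at 551 ± 8.45 and Hsph1 at 281 ± 47.1 CPM. Immediate early genes, which neurons induce within minutes of activity, summed to 475 ± 1.502 CPM (Junb 257 ± 16.1, Egr4 48.4 ± 16.4 and Dusp1 44.9 ± 5.57 CPM). Long noncoding RNAs of the list summed to 275 ± 35.1 CPM (Malat1 110 ± 30.9, Pantr1 66.1 ± 9.64 and Snhg11 24.8 ± 2.15 CPM). Of the 32 lists, 16 had a summed mean of 1000 CPM or more.

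**Figure D2:**
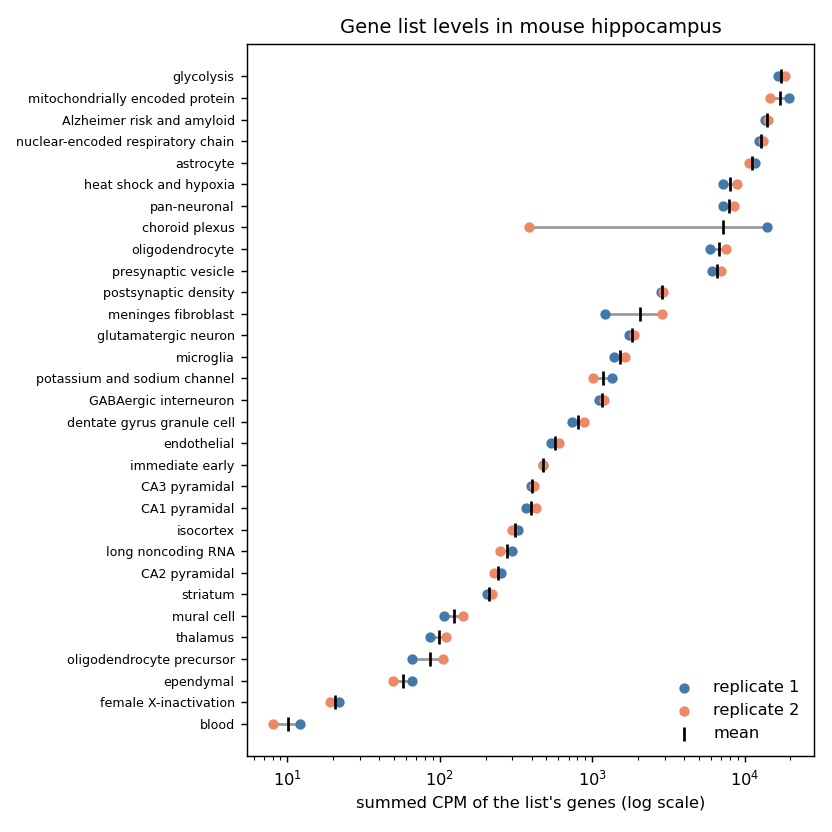
Summed CPM of each gene list on a log axis, with 1 point per library, a tick at the mean and a line between the libraries. The choroid plexus list spans 14012 CPM in replicate 1 and 387 CPM in replicate 2, and the list of Y-linked genes is left out because it held 0 reads.

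Replicate 1 differed from replicate 2 above all in genes of the choroid plexus, the epithelium that makes cerebrospinal fluid. All 12 genes of that list had a higher CPM in replicate 1, and together they reached 14012 CPM there against 387 CPM in replicate 2, a ratio of 36.2. Ttr was 153-fold higher (15914 against 107 reads). The lysophospholipase Enpp2 was 7.19-fold higher (2136 against 305 reads), and the folate receptor Folr1 20.1-fold higher (98 against 5 reads). Of the 10 members with enough reads for the test, 10 were higher in replicate 1 by Fisher's exact test, whether adjusted over all genes or adjusted over the list alone. Igfbp2 was 2.74-fold higher (log2 ratio 1.46, 1.11 to 1.81), and Kcne2 was at least 13.7-fold higher (40 against 0 reads, against the floor of 3 reads per library). By edgeR's exact test 9 of the 12 members passed.

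Over all genes, 707 of 11891 tested differed between the libraries by Fisher's exact test with Benjamini-Hochberg adjustment, 305 higher in replicate 1 and 402 higher in replicate 2. The split depended on the scaling. With edgeR's TMM library sizes 352 were higher in replicate 1 and 305 in replicate 2, and with DESeq2's size factors 352 and 304. Without genomic and incomplete reads the split was 162 and 357. At a ratio of at least 2-fold, 203 genes differed, 132 higher in replicate 1 and 71 higher in replicate 2. By edgeR's exact test, which uses the dispersion between the libraries and TMM library sizes, 50 genes differed, 37 higher in replicate 1 and 13 higher in replicate 2. These tests set 1 library against 1 library and compare the libraries, not conditions. Of the 203 genes, 86 had most of their reads on single-exon models, and 67 of these were higher in replicate 1.

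**Figure D3:**
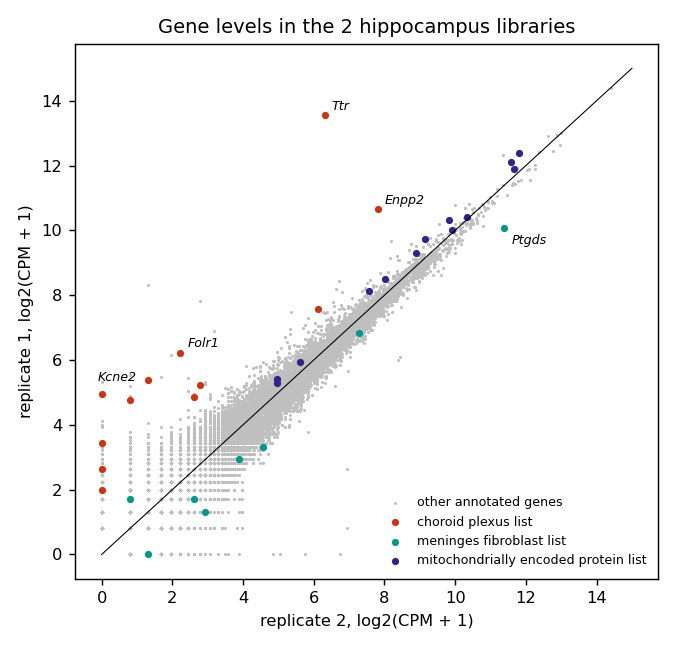
Gene levels in replicate 1 (vertical) against replicate 2 (horizontal), as log2(CPM + 1), with each gene as a point, the genes of 3 lists in colour and the line of equality. Ttr, at 11964 and 78.3 CPM, and Enpp2, at 1606 and 223 CPM, lie far above the line, and Ptgds, at 1073 and 2680 CPM, lies below it.

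Among the 10 genes with the highest ratio in replicate 1, Ttr, Folr1 and Enpp2 belong to the choroid plexus list. A potassium channel gene, Kcnj13 (chromosome 1, 87386363 to 87394729), was 38.3-fold higher with 298 against 8 reads, and 1500015O10Rik was 14.6-fold higher with 156 against 11 reads. Ppp1r16b, Dpysl2, Klhl3 and Inpp4a were 4.41-, 3.30-, 3.14- and 2.98-fold higher, but 92.8%, 99.3%, 97.7% and 96.2% of their reads were single-exon. For Ppp1r16b the log2 ratio of 2.14 became -1.06 without genomic and incomplete reads, which did not pass the test. BC065397 had 419 against 2 reads (log2 ratio 7.75, 5.89 to 10.80), of which 416 lay outside its annotated span.

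Of the 10 genes with the highest ratio in replicate 2, Ptgds had the most reads. This prostaglandin D synthase, made by the meninges and choroid plexus among other cells (chromosome 2, 25466709 to 25470046), had 1427 against 3661 reads and was 2.498-fold higher in replicate 2. Cystathionine synthase Cbs was 2.66-fold higher, C1qtnf4 2.51-fold, Grb14 2.12-fold and Riox1 2.07-fold. Of these 5, only Ptgds passed edgeR's exact test (adjusted p = 0.0396). The other 5 have uncertain assignments. Gm45837 (7 against 165 reads) overlaps Pde2a, which was 2.82-fold higher in replicate 1. Gm49450 (1 against 166 reads, log2 ratio -7.34, -12.65 to -4.84) shares 87.5% of its 25-base words with Tuba1a. Rpl21-ps9, at least 47.4-fold higher in replicate 2 (0 against 146 reads), had 145 of its reads outside its annotated span. Of the 452 reads of Parp6 in replicate 2, 322 lay outside its annotated span, and 98.6% of the reads of Macrod1 (90 against 474) were single-exon.

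Of the 29 lists with at least 3 testable members, 4 had a median log2 ratio outside the central 95% of 10000 random lists of matched size and expression. About 5% would fall outside by chance, and the percentile describes these libraries. The choroid plexus list had a median of 3.70 (random range -0.33 to 0.23). Mitochondrially encoded protein genes had a median of 0.45 (-0.27 to 0.06). Of these 13 genes, 8 were higher in replicate 1, with the same count adjusted over the list alone, such as mt-Nd1 (log2 ratio 0.57, 0.52 to 0.62) and mt-Co1 (0.52, 0.46 to 0.58). None of them passed edgeR's exact test, which called 50 genes over the whole annotation and 439 at an unadjusted p under 0.05. The meninges fibroblast list, with 2046 ± 1184 CPM in sum, had a median of -1.09 (-0.46 to 0.36). Ptgds was its only call over all genes, and 3 members were higher in replicate 2 adjusted over the list alone. The collagen-binding protein Dcn had 151 and 209 reads, and the transporter Slc6a13 had 12 and 31. The oligodendrocyte precursor list had a median of -0.75 (-0.42 to 0.46). Its 1 call, over all genes and adjusted over the list alone, was Olig2 (27 and 61 reads), which did not pass edgeR's exact test, and only 6 of its members had enough reads for the test.

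**Figure D4:**
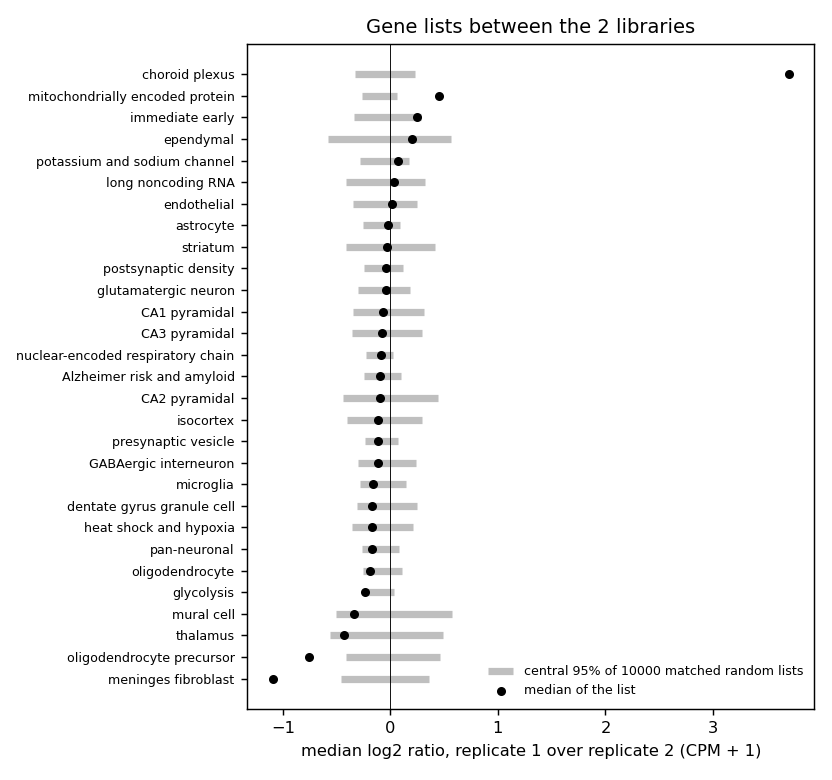
Median log2 ratio of each gene list, replicate 1 over replicate 2 on CPM + 1 (black points), against the central 95% of 10000 matched random lists (grey bars). The choroid plexus list (3.70) and mitochondrially encoded protein genes (0.45) lie above their bars, and the oligodendrocyte precursor (-0.75) and meninges fibroblast (-1.09) lists lie below.

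The other 25 lists lay at percentiles from 4.29 to 96.45. Over all genes, 8 of 15 glycolysis genes were higher in replicate 2 and 1 in replicate 1, or 11 and 1 adjusted over the list alone. For presynaptic vesicle genes 6 of 18 were higher in replicate 2 and 2 in replicate 1, or 7 and 2 adjusted over the list alone. Cplx2, one of the latter, had a log2 ratio of 0.37 that became -0.55, no longer past the test, without genomic and incomplete reads. Of the 12 oligodendrocyte genes 4 were higher in replicate 2 and 1 in replicate 1, or 4 and 2 adjusted over the list alone. Of the 12 pan-neuronal genes 4 were higher in replicate 2 and 1 in replicate 1, or 6 and 1 adjusted over the list alone, and of the 12 astrocyte genes 1 and 2, or 2 and 4. One of the latter, Slc1a2, had a log2 ratio of 0.25 that became -0.10, no longer past the test, without genomic and incomplete reads. Of the Alzheimer's disease genes, 4 of 15 were higher in replicate 2 and 0 in replicate 1, or 5 and 1 adjusted over the list alone. Nuclear-encoded respiratory chain genes had 3 of 17 higher in replicate 2 and 1 in replicate 1, or 4 and 1, and heat shock genes 2 of 6 higher in replicate 2 under both adjustments. None of these calls passed edgeR's exact test.

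Single calls or none were made in the remaining lists. Microglial genes had 1 of 12 higher in replicate 2, or 3 adjusted over the list alone. Glutamatergic, dentate gyrus granule cell, endothelial and postsynaptic density lists each had 1 member higher in replicate 2 under both adjustments. These were Camkv, Calb1, Cldn5 and Ddn. The isocortex, channel and long noncoding RNA lists each had 1 member higher in replicate 1 under both adjustments. These were Rorb, Scn2b and Malat1, and the log2 ratio of Rorb, 1.31, became -0.12, no longer past the test, without genomic and incomplete reads. The mural cell list had 0 calls over all genes and 1 adjusted over the list alone. The GABAergic, CA1, CA2, CA3, ependymal, thalamus, striatum and immediate early lists had 0 calls by Fisher's exact test under both adjustments. No blood gene had enough reads for the test. None of the single calls of these lists passed edgeR's exact test.

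No read fell on a Y-linked protein-coding gene, although the tissue was labelled male. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both libraries, which allows up to 2.26 CPM each in replicate 1 and 2.20 CPM in replicate 2. Their homologs on the X chromosome, Ddx3x, Eif2s3x, Kdm5c and Kdm6a, together had 219 and 231 reads. Xist, the noncoding RNA that silences an X chromosome in females (X, 103460366 to 103483254), had 27 and 25 reads, or 19.3 ± 1.41 CPM, and its antisense partner Tsix had 2 and 1 reads. Xist did not differ between the libraries by Fisher's exact test, over all genes or adjusted over the list alone, and Tsix had too few reads for the test. No Xist read was spliced, and 25 and 23 of them were placed on 1 unspliced model of 849 bases at its annotated 5′ end. A strand setting of the library preparation is not given in the sources used here, so reads of Xist and Tsix in the region they share are uncertain. Of the 183 protein-coding genes annotated on the Y chromosome, none held a read in either library.

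Most of the 50 genes fixed for their known isoforms were led by 1 transcript that took about the same place in both libraries. Of 46 with at least 20 reads in each library, 37 were led by an annotated transcript, and the median share of the leading transcript was 53.1%. The leading shares of these 46 genes leave out reads of the genomic class. Apoe-206 held 95.1% ± 0.146 of the reads of Apoe, Actb-201 held 87.1% ± 1.08 of those of Actb, and Rtn1-201 held 81.8% ± 2.21 of those of Rtn1. For Actb the share rests on 1069 of 6782 reads in replicate 1 and 1196 of 3547 in replicate 2. Actb-201 held 923 and 1051 reads. In the myelin gene Mbp (chromosome 18, 82475146 to 82585637) the 5-exon transcript Mbp-211 held 64.7% ± 2.73 and the 6-exon Mbp-212 held 12.9% ± 1.33. Snap25-201 held 77.9% ± 3.12 of the reads of Snap25, against 6.23% ± 1.18 on Snap25-202. App-201 led App with 51.2% ± 2.97, Clu-201 led Clu with 52.6% ± 1.45, and Cdc42-202 led Cdc42 with 38.5% ± 3.12. In Atp2b1, a plasma membrane calcium pump, an unannotated combination of 6 exons (chromosome 10, 98914406 to 98991202) led with 53.6% ± 2.96. This model had 5 introns, against 8 in its nearest annotated transcript, and may be truncated. Ntrk2, the receptor for brain-derived neurotrophic factor, was led by the 12-exon Ntrk2-202 (39.6% ± 2.65), while the 18-exon Ntrk2-201 held 5.52% ± 0.979.

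Between the libraries, the leading share of 14 of the 46 genes differed by Fisher's exact test adjusted over the list alone, and of 11 when adjusted over all genes. Pkm-202 held 66.0% (64.1 to 67.9) of the reads of the pyruvate kinase gene in replicate 1 and 79.4% (77.9 to 80.8) in replicate 2. Parp6 ends before Pkm starts on the same strand of chromosome 9. Outside its annotated span Parp6 had 0 reads in replicate 1 and 322 in replicate 2. Whether these reads belong to Pkm was not tested, so the difference for Pkm is uncertain. Rtn3-203 held 60.1% (56.5 to 63.6) against 76.8% (73.5 to 79.8), Psap-201 held 40.7% (37.0 to 44.4) against 419 of 838 reads (46.6 to 53.4%), and Gnas-208 held 45.9% (42.0 to 49.8) against 55.8% (52.3 to 59.3). Ndrg2-202 held 42.8% (40.6 to 45.1) against 37.0% (35.0 to 39.0). Of the 15 genes with most reads, Mbp, Snap25 and Rtn1 also differed, and the largest of these 3 differences was -4.42 percentage points in Snap25 (replicate 1 minus replicate 2). For Mbp, Snap25, Syn2 and Rtn3 the direction turned when only annotated transcripts were counted, and the turned differences did not pass the test. With annotated transcripts alone 5 of 40 genes differed, and without incomplete models 4 of 42.

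The remaining 31 of the 46 genes had fewer reads. Cplx1-201 held 91.4% ± 1.75 of the reads of Cplx1, the highest share among them, and an unannotated combination held 11.8% ± 2.30 of those of Ncam1, the lowest. In Camk2a, single-exon incomplete reads led with 54.7% ± 4.74, ahead of Camk2a-203 with 26.3% ± 4.88. Mapt-204 held 59.5% ± 2.86 of the reads of the tau gene and Gria1-202 held 32.5% ± 2.93 of those of Gria1.

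**Figure D5:**
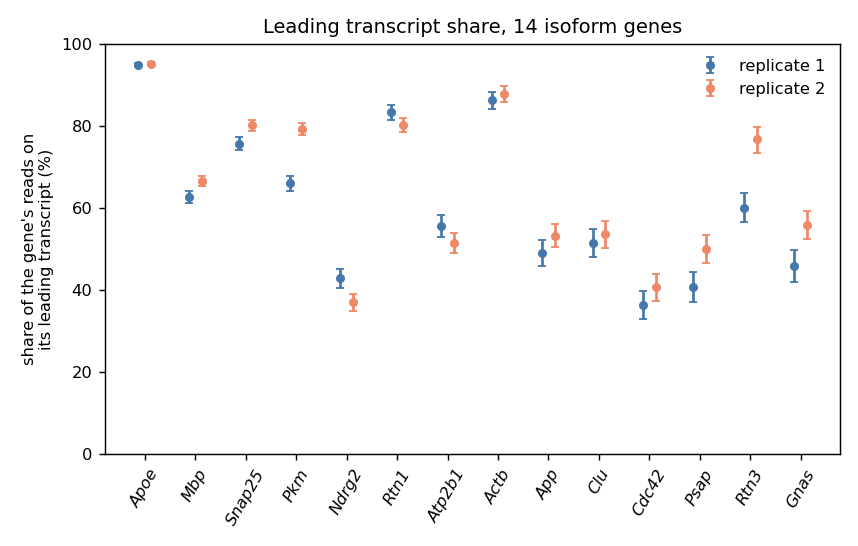
Share of a gene's reads (%) on its leading transcript in each library, for 14 of the 15 isoform genes with most reads, with 95% Clopper-Pearson intervals. Reads of the genomic class are left out of the share. Apoe is highest at 94.98% and 95.19%, and Rtn3 differs most, with 60.1% in replicate 1 and 76.8% in replicate 2.

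Over all 6262 genes with at least 20 reads in each library, the leading transcript held a median of 70.3% of the reads. It was an annotated transcript in 5174 genes, incomplete reads in 845 and an unannotated spliced model in 243. The leading transcript held less than 50% of the reads in 1797 genes and more than 90% in 1183. Its share differed between the libraries in 200 genes by Fisher's exact test. The 10 genes with the largest difference were Nudt3, Clasp2, Ywhag, Gnb1, Cplx2, Cep170b, Spin1, Tmem263, Nr3c2 and Tmem181a, and in each the leading model was single-exon incomplete reads. In Gnb1 these held 2322 of 2363 reads in replicate 1 and 4 of 40 in replicate 2, while the genomic class, which stays out of the share, held 2 and 1365 reads of the gene. In Nudt3 they held 419 of 444 reads against 0 of 29, beside 0 and 219 genomic reads. With spliced models alone 29 of 5846 genes differed, and with annotated transcripts alone 7 of 4541. Several annotated transcripts were found together in a part of the genes. Of 9273 genes with at least 10 reads in each library, 1389 (14.98%) had 2 or more annotated transcripts with at least 5 reads in each. Gpm6b had 8 such transcripts, and Mtch1, Mbp, App and Hpca had 6 each.

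Unannotated spliced transcripts found in both libraries mostly joined known splice sites. With at least 2 reads in each library and an identical chain of introns, 4340 models of 2642 genes were shared, 2480 of them combinations of annotated splice sites in both libraries and 1411 with an unannotated splice site in both. Replicate 1 held 35599 unannotated spliced models of 1 or more reads and replicate 2 held 38563. The most abundant shared model was the transcript of Oaz1, ornithine decarboxylase antizyme, which regulates polyamine synthesis. This 5-exon model (chromosome 10, 80826656 to 80829284) held 2361 and 2502 reads, 94.9% ± 0.144 of the gene. It differed from the annotated Oaz1-201 by lacking an annotated gap of 4 bases (80828292 to 80828295). Its relative Oaz2 showed the same at 65686269 to 65686272 of chromosome 9, with 411 and 523 reads (84.5% ± 0.384 of the gene). No model with reads recorded a gap as short as 4 bases, so the models cannot show whether reads of these genes lacked them.

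In the other 8 of the 10 most abundant, an intron or its edge differed. Dctn2, a dynactin subunit, used an intron on chromosome 10 that began at 127267493 in place of 127267483 in 74.5% ± 1.63 of its reads. Vdac3, a channel of the outer mitochondrial membrane, used an intron on chromosome 8 from 22583737 to 22587548 in place of 22583737 to 22587552 in 78.6% ± 1.94 of its reads. In Mpc1, a mitochondrial pyruvate carrier subunit, a 4-exon model with a first intron of 12573 bases held 89.8% ± 0.0856 of the reads. Bsg had a model with an unannotated splice site in 15.9% ± 0.890 of its reads. Unannotated combinations held 51.3% ± 0.231 of the reads of Atp2b1, 41.4% ± 2.49 of Apbb1, 30.6% ± 0.765 of Hnrnpk and 13.3% ± 1.77 of Ndrg2. These shares are of all reads of the gene, the genomic class included. The model of Atp2b1 may be truncated, as it ended at the base before an annotated intron. In the models of Hnrnpk and Bsg, an intron left out a short exon of the nearest annotated transcript. Alignments were not used here, so how reads were aligned around these short exons was not checked.

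An unannotated model led all spliced models outside the incomplete class in 670 of 6626 genes (10.1%, 9.40 to 10.9) in both libraries. In 303 of these genes it was the same model. Unannotated models were not screened for completeness, so some can be truncated. For example, the models of Atp2b1, Kif5c, Ndufa13 and Atp5f1 had 5, 10, 3 and 5 introns. Their nearest annotated transcripts had 8, 25, 4 and 7. The model of Atp2b1 ended at 98991202, and an annotated intron starts at 98991203. After Oaz1 and Atp2b1, the genes with most reads were Ttc3, Kif5c, Hnrnpk, Sept7, Apbb1, Ndufa13, Atp5f1 and Celf4. In Kif5c and Atp5f1 the leading model held 0.909% ± 0.344 and 0.751% ± 0.130 of all reads of the gene. Ndufa13 was led by a different model in each library. In Ttc3, Sept7 and Celf4 the leading model held 9.67% ± 2.33, 26.8% ± 6.29 and 12.6% ± 0.596. Where incomplete models were allowed to lead, 264 genes were led by an unannotated model.

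Most loci outside the annotated genes that both libraries shared were antisense to a gene. With at least 2 reads in each library and overlap on the same strand, 1727 loci were found in both, 1403 antisense and 324 intergenic, and 219 of them had more than 1 exon. The largest antisense locus lay opposite Map1b on the plus strand of chromosome 13, with 4391 and 2650 reads. It was followed by loci opposite Actb (3950 and 1866 reads), Gnb1 (2151 and 1195 reads), Ncs1 (1885 and 1253 reads) and CT010467.1 (1377 and 1622 reads). The largest intergenic locus lay on the minus strand of the mitochondrial genome (15422 to 16187 in replicate 1) with 288 and 179 reads. The next 4 were on chromosomes 16 (28156227 to 28160098, 173 and 120 reads), 4 (133095726 to 133101547, 167 and 105 reads), 2 (180719362 to 180721595, 142 and 65 reads) and 11 (100457022 to 100461696, 129 and 68 reads). Strand is uncertain for these loci, since nearly all antisense reads were unspliced.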

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

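The tests of the scaling, of the choroid plexus tissue, of the amount of unspliced reads, of spliced antisense transcription and of the Y-linked genes were chosen only after the results were seen, whereas the tests on annotated transcripts alone and on shared ends were set beforehand. The design holds 1 group, so it gives no biological difference between groups to set against these explanations.

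Choroid plexus genes stood far higher in replicate 1, led by Ttr (11964 against 78.3 CPM) and Enpp2 (1606 against 223 CPM). A total distorted by a few abundant genes is argued against, since the median log2 ratio of the list was 3.73 under edgeR's TMM scaling. Misplaced unspliced or incomplete reads are argued against in the same way, by a median of 3.87 on annotated transcripts alone. Tissue of the choroid plexus in the sample of replicate 1 is a candidate explanation that stays open: all 12 members were higher there, which was known when the test was chosen and adds no support of its own, and together they took 1.40% of its reads against 0.0387% in replicate 2. The labels give hippocampus for both samples and name no sort or gate, none of the 12 genes belongs to another list, and 8 of them also had reads in replicate 2.

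Reads on antisense loci were more frequent in replicate 1, and counted over all models of these loci 98.3% and 97.7% were unspliced. Spliced antisense transcripts made up only 0.824% of the difference, and the amount of unspliced reads alone is argued against because the ratio of antisense to genomic reads was 1.38 times higher in replicate 1. If the strand of unspliced reads had not been resolved, over 50% of the single-exon antisense reads were predicted to share both ends, within 50 bases, with an unspliced model on the opposite strand. The shares were 41.75% and 38.42%, short of that bound, but 71.1% and 73.0% of the reads overlapped such a model over most of their length, a measure not set beforehand, so the bound on shared ends was too strict to exclude this. The test describes each library and not the difference between them, and the explanation stays open.

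Y-linked genes had no reads although the mice were described as male. Absence from the annotation is argued against, since all 4 listed genes are in the deposited annotation of both libraries. Too little depth stays open: the 4 homologs on the X chromosome had 450 reads over both libraries, but the usual level of the Y-linked genes in this tissue is not in the tables used here. Tissue of a female animal is a candidate explanation that also stays open: the Xist locus had 27 and 25 reads, but these were known when the test was chosen, so it adds no support of its own. In addition no Xist read was spliced and the strand of the shared region with Tsix is uncertain.

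Reads of 3 further kinds were part of the totals but were not compared as kinds of their own, and each lay above the limit that a count of 0 allows. Unplaced or unlocalized scaffolds held 270 and 272 reads. Incomplete models that matched the 3′ part of an annotated transcript held 96092 and 101312 reads, and those that matched the 5′ part held 47610 and 48900 reads.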

How the results depend on the processing

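Of the alternatives, edgeR's exact test, the totals of annotated genes or without the choroid plexus list, the separate and the spliced models, and overlap on either strand were chosen after seeing the data. Unless stated, the cause of a change was not tested. The count of 707 genes was 657 with TMM, 656 with DESeq2, 602 with no minimum, 519 without genomic and incomplete reads, 658 with annotated totals and 664 without the choroid plexus list. Of these, 610, 609, 602, 418, 626 and 648 were among the 707. It fell to 203 with a 2-fold minimum, by construction, and to 50 with edgeR's exact test, which changes the test, the scaling and the error together. The number of shifted lists was 4 under all 4 alternatives run. Pearson's r of 0.954 became 0.948 for genes with 10 or more reads over both libraries, 0.980 with a pseudocount of 10 CPM, and was 0.954 with TMM. Genes detected in both libraries numbered 11207 at 5 reads, 12793 without genomic and incomplete reads and 14957 after thinning.

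The share of annotated transcripts, 68.2%, was 67.0% without mitochondrial genes, and became 15.26% with each model counted once and 73.67% without the genomic class, by construction of the total. Their median length became 2055.5 bases with each model counted once. The median leading share of the isoform genes rose from 53.1% to 80.89% with annotated transcripts alone and to 71.56% without incomplete models, again from a smaller total, and was 52.5% with separate models. The 200 genes that differed in leading share became 7 with annotated transcripts alone, 29 with spliced models alone and 317 with unspliced incomplete models kept apart in each library, and 150 at 50 reads. Genes with several annotated transcripts numbered 2424 at 2 reads and 832 at 10 reads, against 1389 at 5. Unannotated spliced models numbered 10639 at 1 read and 1430 at 5 reads, against 4340 at 2, and 0 when matched by identifier, because identifiers carry the library. Genes led by an unannotated model fell from 670 to 320 at 50 reads and to 264 when incomplete models competed. Loci fell from 1727 to 799 at 5 reads, and were 1288 at 50% reciprocal overlap and 1801 on either strand.

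Direction was compared only for genes past the test in the main setting, and for leading shares only where the leading model stayed the same. Without genomic and incomplete reads, log2 ratios of such genes changed direction for Ppp1r16b (-1.06), Actb (-0.10), Cplx2 (-0.55), Slc1a2 (-0.10) and Rorb (-0.12). Differences in leading share, in percentage points, changed direction with annotated transcripts alone for Mbp (0.0245), Snap25 (1.48), Syn2 (0.599) and Rtn3 (1.31), and without incomplete models for Snap25 (1.96), Syn2 (0.0656) and Rtn3 (2.36). None of these turned values passed the test. Over the 763 log2 ratios of named genes computed under an alternative, 691 kept their side of the threshold, 59 lost the call (43 with edgeR's exact test) and 8 gained it. Direction was not compared for genes without a call in the main setting. Of 119 leading shares 103 did so, 7 lost and 2 gained the call, and all 116 list shifts were kept. List levels moved by less than 1 SD in 32 of 32 lists with TMM scaling and in 13 of 32 without genomic and incomplete reads.

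With each library alone the ranges were 66.3% to 70.1% for annotated transcripts, 16649 to 16939 genes, 15 to 16 lists of 1000 CPM or more, 52.1% to 53.7% for the leading share, 1645 to 1746 genes with several annotated transcripts, 980 to 983 genes led by an unannotated model and 1612 to 1784 bases. With 2 libraries, 1 SD always covers either value, so these ranges are no test of stability. Results that compare or intersect the libraries have no value with a library left out. Depth should limit genes of few reads most, but recovery by the gene test was not split by read count. With counting error alone, Fisher's exact test recovered 41.8% of all simulated 2-fold changes.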

Other observations

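The gene families, genes and models named here were chosen after their values were seen, and the families were not tested. Cytosolic ribosomal protein genes were among the most abundant families of the tissue. The 82 detected genes summed to 39091 ± 1734 CPM, or 3.91% of all reads, led by Rpl3 (2227 ± 126.7 CPM), Rpl41 (1309 ± 45.2 CPM) and Rps6 (1204 ± 87.4 CPM). The 39 proteasome subunits, which form the main protease of the cytosol, summed to 7124 ± 86.1 CPM, with Psmc5 at 464 ± 0.385, Psmb1 at 409 ± 1.70 and Psmb5 at 352 ± 17.5 CPM. The 7 β-tubulin genes, which build microtubules, summed to 5656 ± 595 CPM, from Tubb2a, Tubb5 (1241 ± 172 CPM) and Tubb4b (643.5 ± 38.2 CPM).

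Receptors of fast synaptic transmission were present at lower levels. The 15 ionotropic glutamate receptor genes summed to 1327 ± 29.95 CPM, led by the AMPA receptor subunits Gria2 (552 ± 4.24 CPM) and Gria1 (216 ± 10.9 CPM) and the NMDA receptor subunit Grin2b (172 ± 4.31 CPM). The 13 GABA-A receptor genes summed to 1075 ± 127 CPM. Their leading members were Gabra5 (224 ± 57.1 CPM), a subunit enriched in hippocampus, and Gabrb1 (222 ± 10.5 CPM). The 16 voltage-gated calcium channel subunits summed to 381 ± 31.1 CPM, with Cacnb4 at 114 ± 29.8 CPM, Cacna1e at 55.2 ± 9.97 CPM and Cacna2d1 at 51.6 ± 6.75 CPM. Genes of the major histocompatibility complex, 18 in number, summed to 290.5 ± 11.3 CPM, led by H2-D1 (135 ± 0.990 CPM), H2-K1 (36.4 ± 9.08 CPM) and H2-DMa (35.6 ± 3.52 CPM).

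Of the 200 genes that differed in leading share, 139 were led by an annotated transcript and 49 by unspliced incomplete reads, but 29 of 5846 genes differed with spliced models alone and 7 of 4541 with annotated transcripts alone. Reads of the genomic class are left out of the shares that follow. Kdelr2-201 held 95.6% (84.8 to 99.5) of the reads of Kdelr2 in replicate 1 and 35.8% (27.8 to 44.4) in replicate 2, yet 95.6% and 96.1% of its spliced reads. Hdac11-201 held 26.1% (14.3 to 41.1) against 85.3% (68.9 to 95.05), and the difference among spliced reads, 57.1% against 85.3%, did not pass Fisher's exact test (adjusted p = 0.59). Gmppb-202 held 76.9% (56.35 to 91.0) of the reads of Gmppb against 22.9% (12.03 to 37.3), with the same shares among spliced reads (Fisher's exact test, adjusted p = 0.00562).

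In Oaz1, 2467 and 2615 reads lay on models that span the 4 bases that the annotation leaves out as a gap, and 0 on models with the gap. In Oaz2, 454 and 580 reads lay on models that span the 4 bases, and 0 on models with the gap. Of 141767 annotated transcripts, 277 have a gap of 10 bases or fewer, and none of these transcripts held a read in either library. The shortest intron was 45 bases in annotated models with reads and 34 bases in the others. No model therefore recorded a gap as short as 4 bases, so these counts cannot show whether reads lacked the 4 bases. The minus strand of the mitochondrial genome outside annotated genes held 2503 and 1217 reads. On the Y chromosome 12 and 3 reads fell on genes of any kind, of which 7 and 2 lay on the pseudogene Gapdh-ps15.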
